A study of Homo sapiens with 4 samples.

How the data were processed

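RNA of growing and of senescent human activated hepatic stellate cells was hybridised to 4 Affymetrix arrays, each prepared from 10 µg of total RNA per the labels. The deposited table gives 1 value per probe set and array on the log2 scale. The values were made with GCRMA, per the submitters' processing notes; its version is not given in the sources used here. GCRMA corrects background by probe sequence, normalizes quantiles between arrays and summarises probes into probe sets on the log2 scale. That the scale is log2 was read from the deposited values, which run from 0.86 to 15.62. The array medians over 54675 probe sets were 2.78 in growing replicate 1, 2.77 in senescent replicate 1, 2.74 in growing replicate 2 and 2.78 in senescent replicate 2, and genes were not centred. Quantile normalization holds the overall distribution of the arrays equal, so a shift of most genes in 1 direction would not show. GCRMA draws dim probe sets together near the bottom of the scale, and very bright ones are compressed near the top, so fold changes at both ends are understated or uncertain. Scanner files were not used here, so no other background correction was tried, and scan dates were not analysed here. For arrays, no read depth exists; the number of arrays limits the precision.

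Genes were named from the platform annotation given with the table: 41097 probe sets had 1 gene symbol, 1801 had several and were not used, and 11777 were not listed and stay unnamed here. Of those with 1 symbol, 41043 matched a current gene record by Entrez ID and 0 symbols changed. The genome build is not given in the sources used here, so no coordinates are printed. Genes on the Y chromosome and XIST were left out of every table. For each of 19740 genes, the probe set with the highest mean over all 4 arrays was kept, and a gene was tested when that probe set reached log2 4 on at least 2 arrays, whichever group these were in, which left 9706 genes. Among called genes with more than 1 bright probe set, 32 of 392 had a probe set of the other sign.

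Groups and replicate numbers were taken from the sample titles. Senescent minus growing was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with no covariate, since the labels state no model, and with Benjamini-Hochberg adjustment over the 9706 genes and a threshold of 0.05. A second count required an absolute log2 change of at least 1. With 2 residual and 1.58 prior degrees of freedom, the spread of a gene is measured poorly; an exact permutation test of a single gene could not reach a p below 0.333. Each of the 24 pathway lists and 7 cell type lists, written from textbook knowledge, was tested against the other genes with limma's camera at its preset correlation of 0.01, adjusted over the 30 lists with a member tested, and members were also counted adjusted over the list alone. Camera passed 11 lists at the preset and 0 with an estimated correlation, for which the arrays leave 2 residual degrees of freedom. "Dim" below means that a gene missed the filter at log2 4. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

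The tests, filter, lists, alternatives and rule for named genes were fixed before the data were examined. Named were the 10 genes with the largest increase and the 10 with the largest decrease among those that passed and whose senescent values both lay on the same side of both growing values, in each pathway list the 4 tested members with the largest absolute change whether or not they passed, and genes chosen in advance (CDKN1A, CDKN2A, CDKN2B, LMNB1, MKI67, ACTA2, COL1A1, MMP1, MMP3, IL6, CXCL8, MICA, ULBP2, CD58 and ICAM1). Other genes are named where 6 or fewer members of a list passed in a direction, or as cell type markers; they were chosen after their values were seen, as were H1-3 and the further genes of the closing section. In the report they are RPA2, MCM6, GINS2, H2BC21, H2BC12, TIGAR, CCL7, TNFRSF11B, PLAT, VEGFA, DCN, LOXL2, P4HA1, P4HA3, MMP10, MMP14, MMP16, TIMP1, CSTB, LRRC17, IFI27, GBP2, CTSL, CTSA, NPC2, GUSB, NSDHL, PRDX1, GPX1, TEK, LYZ, KRT7, CALB2, LMOD1 and MCAM. Not reported here are 1 gene fixed in advance and 1 list member that the rule names.

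The alternatives were the replicate number as a block, no filter and a stricter filter at log2 6, values under log2 4 raised to 4, quantile normalization, subtraction of array medians, the mean of all probe sets of a gene (dim ones included), eBayes with trend and robust, each array left out in turn, all probe sets tested, camera with an estimated correlation, and fry, which tests a list against no change and not against the other genes. The series text describes separate preparations that each received the agent or the vehicle, and the titles number the arrays of each group 1 and 2; the number was therefore taken to mark the preparation. The main fit does not pair the arrays of a preparation, and the fit with the block does. Across the 9706 genes, which are not independent replicates, growing 1 minus growing 2 correlated with senescent 1 minus senescent 2 at 0.174 (Spearman 0.136). Whether the preparations came from separate donors is not stated, so p-values measure only the spread between these samples. Pearson correlations of the log2 values over the genes tested were 0.976 for the growing pair, 0.994 for the senescent pair and 0.94 to 0.946 between groups.

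The limma and camera steps were tested on simulated data for senescent against growing: 9706 genes, 20 simulations, 200 changed genes each. They recovered 22.5% of genes changed by 1 log2 unit, 72.3% at 2 and 91.4% at 4. Of the calls, 4.7% were unchanged genes, 0 of 600 random lists passed, and the changed list passed in 20 of 20 runs. Noise was drawn independently for each gene, with the same spread in both groups and no effect of the replicate number. The runs therefore cannot show the error rates for correlated genes or for groups of unlike spread, as in these data. The variances were drawn from the prior that limma fitted to the real arrays, and the changed list held only raised genes. The share of false calls and the list result thus check the steps under limma's own model only.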

Results

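Hepatic stellate cells are the vitamin A-storing mesenchymal cells of the liver, which on activation turn into contractile cells that lay down collagen. Expression was measured on 4 Affymetrix arrays of human activated stellate cells, 2 of growing cultures that received the vehicle and 2 of cultures made senescent by an agent that damages DNA. Senescence is a lasting arrest of the cell cycle in which cells stay alive and secrete a changed set of proteins. Each group holds a replicate 1 and a replicate 2, from separate preparations of cells, so n = 2 throughout. The arrays carried 54675 probe sets, their medians lay between log2 2.74 and 2.78, and 9706 genes were bright enough to be tested. The number of arrays limits the precision: the median standard error of a log2 change was 0.128.

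The comparison asks which genes differ between senescent and growing activated stellate cells. In senescent cells, 29 of 33 transcripts of mitosis fell, as did 10 of 29 collagen and matrix genes and 8 of 24 genes of activation and contractility. With the replicate number as a block, 9, 0 and 0 of them passed. The lists of replication-dependent histones, matrix-degrading proteases, DNA damage response targets, and lysosomal, cholesterol synthesis and oxidative stress genes passed as shifted up, with 3 of 7, 6 of 20, 2 of 29, 5 of 26, 2 of 15 and 4 of 17 members rising singly, or 1, 0, 1, 0, 0 and 0 with the block. None of the 11 lists that passed did so with an estimated correlation (lowest adjusted p = 0.517). CDK1, the kinase that starts mitosis, fell from log2 10.17 ± 0.19 to 4.49 ± 0.75 (SD, n = 2). GDF15, a secreted DNA damage response target of the TGF-beta family, rose from 9.39 ± 0.29 to 13.58 ± 0.12 (SD, n = 2), a change of 4.19 log2 units that was 1.48 as the mean of its probe sets (adjusted p = 0.018), and the collagen gene COL4A1 fell from 13.86 ± 0.13 to 11.85 ± 0.21 (SD, n = 2). Under the block, GDF15 passed (limma, adjusted p = 0.0406), and CDK1 (0.0537) and COL4A1 (0.0624) did not.

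In all, limma called 950 of the 9706 genes at an adjusted p under 0.05, 484 higher and 466 lower in senescent cells, and 538 of them differed at least 2-fold (238 higher, 300 lower). All 950 differed in the same direction within replicate 1 and within replicate 2. The threshold forces this, since a gene passes only if its change is large against the gaps within its groups. It is no separate support. Both senescent arrays lay on the same side of both growing arrays for 64.4% of the genes tested, against 33.3% by chance. With the replicate number as a block, 40 genes passed (22 higher, 18 lower), 39 of them among the 950. Without the filter on dim genes, 383 of 19740 passed. The count was 1524 without growing replicate 1, 395 without growing replicate 2, and 0 without senescent replicate 1 or without senescent replicate 2, where 1664 and 1608 genes had an unadjusted p under 0.05. Without a senescent array, its group is 1 array and all of the spread comes from the growing pair, whose differences had an SD of 0.556 against 0.287 in the senescent pair, so no gene call below passed there. Without a growing array, the lone one left is assumed to vary like the senescent pair, which gives all of the spread. A call gained there rests on that tighter pair and does not support a difference. With a senescent array left out, the change itself stayed between 79.4% and 121% of its value for the 57 named genes that had passed. The threshold bounds this range too, since a gene passes only if its change is large against the gaps within its groups. The range is therefore no separate support. Growing replicate 2 stood apart from growing replicate 1, with 519 genes at least 1 log2 unit apart against 123 in the senescent pair.

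**Figure D1:**
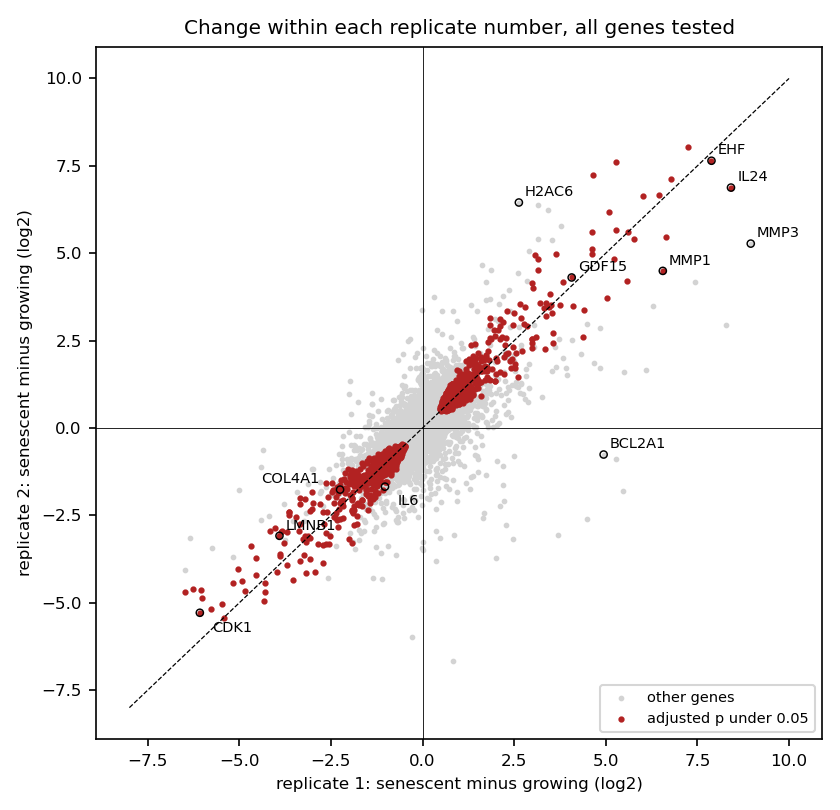
Each point is 1 of the 9706 genes, with its senescent minus growing log2 difference within replicate 1 on the x axis and within replicate 2 on the y axis; red points passed the test and circled genes are named. All 950 red points have the same sign on both axes, which the test threshold forces. The correlation across genes, which are not independent replicates, is 0.767, and BCL2A1 lies at 4.94 and -0.76.

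Among the 10 genes that passed with the largest increases were several that were near background in growing cells. For a gene below log2 4 on both arrays of a group, the change is given as a lower limit, with values under 4 raised to 4. EHF, an epithelial ETS transcription factor, rose by at least 6.39 log2 units (adjusted p = 0.00513), RAB27B, a GTPase of vesicle secretion, by at least 6.92 (adjusted p = 0.00774), and the cytokine IL24 by at least 6.94 (adjusted p = 0.0197). NEFL, the neurofilament light chain, rose by at least 5.46 and HSD11B1, which regenerates active glucocorticoid, by at least 5.25 log2 units. IL13RA2, a decoy receptor for interleukin 13, rose by at least 4.51, the surface protein CD24 by at least 4.73, thrombomodulin (THBD) by at least 5.32 and kynureninase (KYNU) by at least 4.43. SPP1, which encodes osteopontin, rose by 6.44 ± 0.63 log2 units (SE, adjusted p = 0.0319). Under the block, EHF, RAB27B, NEFL, HSD11B1 and IL13RA2 still passed (adjusted p = 0.0406 each), while IL24 (0.0621), CD24 (0.0621), KYNU (0.0621), SPP1 (0.0689) and THBD (0.0771) did not. The probe sets of some of these genes differed: RAB27B had a second at 0.11, NEFL had 3 from 0.55 to 6.95 and KYNU had 3 from 0.85 to 5.62. As means over all probe sets the changes were 2.95 (RAB27B), 3.22 (NEFL) and 2.18 (KYNU), each still passing (adjusted p = 0.018, 0.00939 and 0.0415).

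The mitosis list moved furthest down. Of its 33 members tested, 29 fell, 0 rose and 4 did not pass (31 fell adjusted over the list alone), with a median change of -3.41 log2 units (camera, adjusted p = 1.5e-24, and adjusted p = 0.517 with an estimated correlation). CDK1 changed by -5.68 ± 0.42 log2 units (SE, adjusted p = 0.0235) and PRC1, a microtubule bundler of the central spindle, by -5.44 ± 0.08 (SE, adjusted p = 0.00483). TOP2A, the topoisomerase that untangles replicated DNA, changed by -5.35 ± 0.55 (SE, adjusted p = 0.0324). DLGAP5, NEK2, ASPM, NUF2 and CDC20, which act in spindle assembly, centrosome separation and anaphase onset, fell to below log2 4 on both senescent arrays, a change of at least -4.71, -4.72, -3.86, -4.20 and -3.44. As means over all probe sets, NEK2 stood at -2.75 and ASPM at -1.75 (adjusted p = 0.013 and 0.0137). Outside the list, the phosphatase CDKN3 changed by -5.45 and the hyaluronan receptor HMMR by -5.44 log2 units, or by -5.01 and -4.88 with values under 4 raised to 4, since 1 senescent array of each lay below. MKI67, the proliferation marker, was not tested because its probe set was dim in both groups (means of log2 3.29 and 2.95). Under the block 9 members passed, among them PRC1, NEK2, ASPM and CDC20. The count of falls was 12 without growing replicate 2 and 24 without growing replicate 1.

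DNA replication genes were lower by less. Of 26 members tested, 4 fell, 1 rose and 21 did not pass (9 and 2 adjusted over the list alone), with a median change of -0.34 (camera, adjusted p = 4.17e-05, and adjusted p = 0.517 with an estimated correlation). The 4 that fell were thymidine kinase TK1 (-3.94 ± 0.34, SE, adjusted p = 0.028), thymidylate synthase TYMS (-1.36 ± 0.16, SE, adjusted p = 0.0381), GINS2 (at least -1.25) and the helicase subunit MCM6 (-0.69, and -0.34 without passing as the mean of its probe sets). RPA2, a subunit of the protein that coats single-stranded DNA, rose by 0.80 (adjusted p = 0.0414), and RRM2, a ribonucleotide reductase subunit, had a change of -2.99 ± 0.73 that did not pass (SE, adjusted p = 0.0878), as did RFC3, a clamp loader subunit, at -1.59 (adjusted p = 0.0613). In the homologous recombination and Fanconi repair list, 3 of 12 members fell (5 adjusted over the list alone): BRIP1 changed by -3.29, BARD1 by -2.62 and FANCI by -1.60 log2 units. As means over all probe sets, BRIP1 stood at -1.66 and BARD1 at -1.06 (adjusted p = 0.039 and 0.0387). RAD51AP1 had a change of -3.52 (adjusted p = 0.0662), and the list did not pass (adjusted p = 0.0819, with 0.0403 when no filter was set and 0.00952 without senescent replicate 2). By limma with the replicate block, 0 members of either list passed, with 12 and 6 at an unadjusted p under 0.05. In each list 1 member fell without growing replicate 2 and 2 without growing replicate 1, and RPA2 was not called without growing replicate 2.

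The list of replication-dependent histones was shifted up in senescent cells. All 7 members tested had higher means, 3 of them passing over all genes and 7 adjusted over the list alone, with a median change of 4.54 log2 units (camera, adjusted p = 0.000776, and adjusted p = 0.528 with an estimated correlation). H2BC4 rose by at least 3.20 log2 units (adjusted p = 0.0231), H2BC21 by 4.0 (adjusted p = 0.0357) and H2BC12 by 2.83 (adjusted p = 0.0437). H4C8 (4.83 ± 0.78, SE, adjusted p = 0.05), H1-2 (4.77 ± 1.11, SE, adjusted p = 0.0825) and H2AC6 (4.54 ± 1.32, SE, adjusted p = 0.119) did not pass. A further 7 listed members were dim, such as H1-3 at log2 2.44 to 2.46 on all 4 arrays. The changes of H1-2 and H2AC6 were 6.24 and 6.30 without growing replicate 1 and 3.30 and 2.78 without growing replicate 2. Their calls there rest only on the spread of the senescent pair, an SD of 0.21 for both against 2.08 and 2.49 in the growing pair. H4C8 passed in 7 of 12 alternatives, among them some that keep all 4 arrays. The list median of growing replicate 2 minus growing replicate 1 was -1.80 log2 units. On that spread, 7 members passed without growing replicate 1 and 4 without growing replicate 2; with the replicate block, H2BC4 passed. Genes of the same histone family are alike in sequence, so a probe set can read several of them.

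Genes activated after DNA damage lay higher as a group. Of 29 members tested, 28 had a higher mean in senescent cells, 2 rose and 0 fell (9 and 0 adjusted over the list alone), with a median change of 0.49 (camera, adjusted p = 0.000252, and adjusted p = 0.517 with an estimated correlation). The 2 that rose were GDF15 (4.19 ± 0.18, SE, adjusted p = 0.0149, and 0.0406 with the replicate block) and TIGAR, a fructose bisphosphatase (0.73, adjusted p = 0.0395, and 0.0814 with the block). FUCA1 (2.30, adjusted p = 0.0774) and SPATA18 (1.36, adjusted p = 0.0861) did not pass; both did without growing replicate 1 (2.96 and 1.78, adjusted p = 0.036 and 0.0343). The list had a median of -0.27 for growing replicate 2 minus growing replicate 1. Without growing replicate 1, 13 members rose, and without growing replicate 2, 1 did. CDKN1A, which encodes p21, was already at log2 12.93 ± 0.17 in growing cells and at 13.59 ± 0.01 in senescent cells (SD, n = 2, limma adjusted p = 0.0584, and 0.0473 with trend and robust). CDKN2A, the locus of p16, rose by 0.54 ± 0.08 log2 units (SE, adjusted p = 0.0484, with 0.0994 under the block, 0.0559 with trend and robust and 0.0709 as the mean of its probe sets), and CDKN2B had a change of -0.26 (adjusted p = 0.612), which turned to 0.14 without growing replicate 1. Among 11 cell cycle inhibitors, CDKN2A alone rose and 0 fell (2 higher and 2 lower adjusted over the list alone); the median change was 0.08, the mean -0.13, and camera's direction was down without passing (adjusted p = 0.693). For this list 0 rose and 1 fell without growing replicate 2, and 2 rose and 1 fell without growing replicate 1. GADD45B (-2.13, adjusted p = 0.0584, and passing without growing replicate 1 at -2.63 and without growing replicate 2 at -1.62), CDKN1B (0.78, adjusted p = 0.595, at -0.43 without growing replicate 2 and passing at 1.996 without growing replicate 1) and GAS1 (-0.67, adjusted p = 0.474, and 0.03 without growing replicate 1) did not pass.

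In the list named senescence-associated loss, LMNB1, UHRF1 and HMGB2 fell, HMGA2 rose and 6 of the 10 tested did not pass (3 lower and 1 higher adjusted over the list alone; list adjusted p = 0.0625, with 0.00012 when no filter was set, 0.0461 with the mean of probe sets and 0.0184 without senescent replicate 2). LMNB1, which encodes lamin B1 of the nuclear envelope, went from log2 8.32 ± 0.49 to 4.83 ± 0.09 (SD, n = 2, limma adjusted p = 0.0251). UHRF1, a factor that maintains DNA methylation, changed by -2.76 (adjusted p = 0.0485) and the chromatin protein HMGB2 by -1.71 (adjusted p = 0.0414), or -0.85 as the mean of its probe sets (adjusted p = 0.0463). HMGA2, an architectural chromatin protein known to accumulate in the heterochromatin foci of senescent cells, rose by 2.12 ± 0.10 log2 units (SE, adjusted p = 0.0158). Its 3 probe sets ranged from 0.26 to 2.12, and the mean over all its probe sets, dim ones included, was 0.40 and did not pass (adjusted p = 0.0539). None of these 4 passed with the replicate block, at adjusted p of 0.0624, 0.0769, 0.086 and 0.0587. The number lower was 1 without growing replicate 2 and 1 without growing replicate 1, and the number higher was 2 without growing replicate 2.

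**Figure D2:**
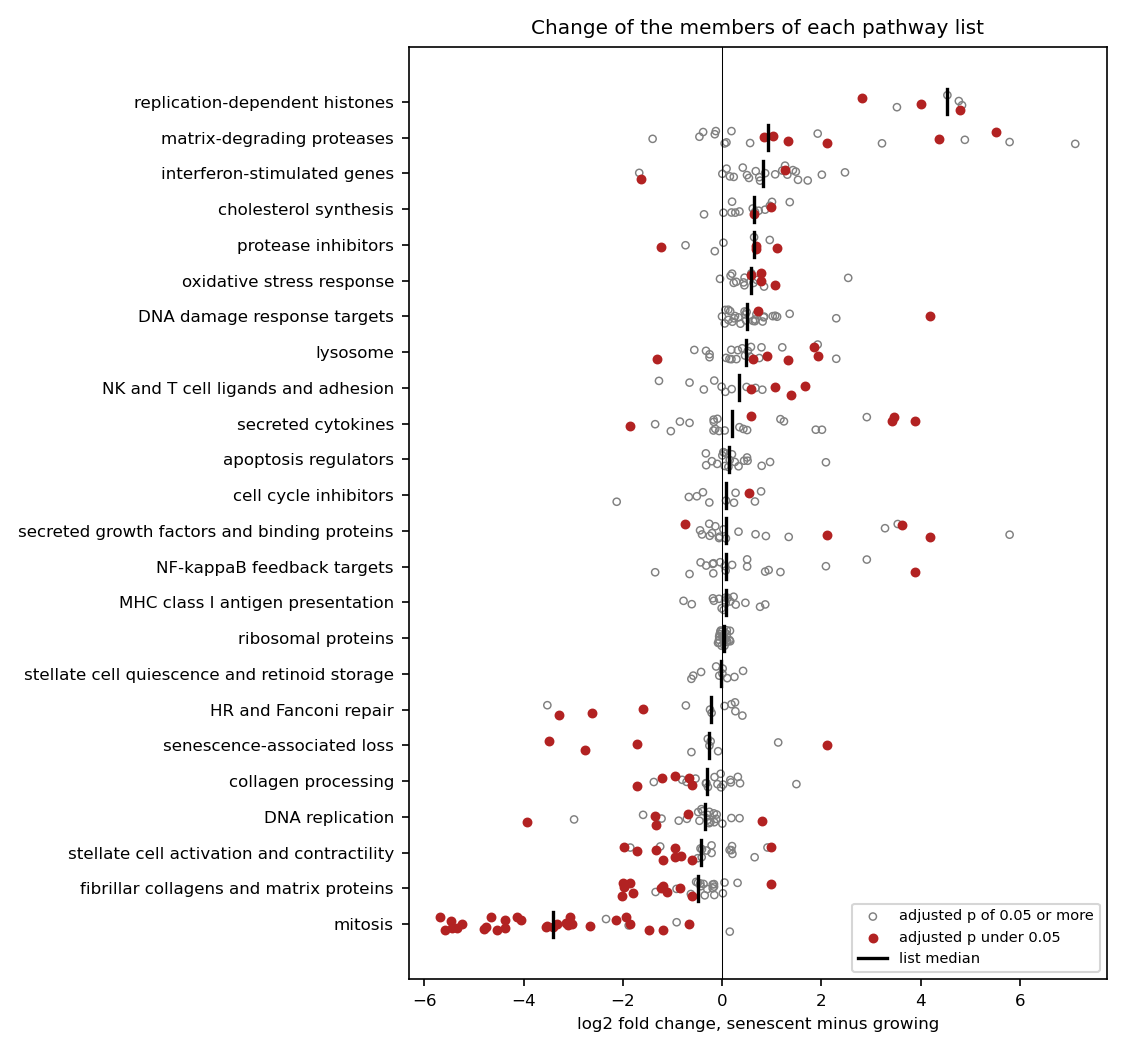
Log2 fold change (x axis, senescent minus growing) of each tested member of the 24 pathway lists, with red points for genes that passed the test, open points for the others and a black bar at the list median. The medians run from -3.41 for mitosis to 4.54 for replication-dependent histones.

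Genes of the senescence-associated secretory set went both ways. Of 24 cytokine genes tested, 4 rose, 1 fell and 19 did not pass (4 and 2 adjusted over the list alone), and the list did not pass (median 0.20, camera adjusted p = 0.506). The neutrophil chemokines CXCL3 (3.89 ± 0.39, SE, adjusted p = 0.0324) and CXCL5 (3.42 ± 0.14, SE, adjusted p = 0.0142) rose, as did the eosinophil chemokine CCL26 (at least 2.05, adjusted p = 0.0324) and the monocyte chemokine CCL7 (0.59, adjusted p = 0.0414). TNFRSF11B, the decoy receptor osteoprotegerin, fell by 1.86 log2 units (adjusted p = 0.0264). CXCL2 had a change of 2.92 ± 0.71 that did not pass (SE, adjusted p = 0.0878). It was 0.98 as the mean of its probe sets, and passed at 1.97 without growing replicate 1 and at 3.86 without growing replicate 2. IL6 stood at log2 13.83 ± 0.03 in growing and 12.47 ± 0.43 in senescent cells (SD, n = 2, limma adjusted p = 0.0568, and 0.0451 with the stricter filter), and CXCL8, the gene of interleukin 8, at 14.47 ± 0.59 and 14.97 ± 0.04 (SD, n = 2, limma adjusted p = 0.363), near the top of the scale in both. The CXCL8 change was 0.09 without growing replicate 1 and 0.92 without growing replicate 2. Growing replicate 2 was higher than growing replicate 1 by a list median of 0.44 log2 units. Leaving out growing replicate 2, the list passed (adjusted p = 0.0112, 6 higher and 0 lower), and without growing replicate 1, 7 were higher and 3 lower. CXCL5 and CCL26 passed with the replicate block.

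Among 21 secreted growth factors and binding proteins, 3 rose and 1 fell (4 and 1 adjusted over the list alone; list median 0.08, adjusted p = 0.576). NRG1, a ligand of the ERBB receptors, rose by at least 3.31 log2 units (adjusted p = 0.0149), GDF15 by 4.19 and the tissue plasminogen activator PLAT by 2.12 (adjusted p = 0.0337), while the angiogenic factor VEGFA fell by 0.76 (adjusted p = 0.0414, and 0.078 as the mean of its probe sets). The urokinase gene PLAU (5.79 ± 1.39, SE, adjusted p = 0.0861) and the KIT ligand KITLG (3.54 ± 1.70, SE, adjusted p = 0.256) did not pass. The PLAU change was 3.95 without growing replicate 1 and at least 6.42 without growing replicate 2, where the growing array left lay below log2 4 (adjusted p = 0.0373 and 0.0343 on the senescent spread). KITLG was at 1.29 without growing replicate 1, passed at 5.79 without growing replicate 2 (adjusted p = 0.0446), and was 0.90 as the mean of its probe sets. The median of growing replicate 2 minus growing replicate 1 was 0.37. Leaving out growing replicate 2, 5 rose and 0 fell, and without growing replicate 1, 4 rose and 3 fell. NRG1 and GDF15 passed with the replicate block. Of 19 NF-kappaB feedback targets, CXCL3 rose and 18 did not pass (1 adjusted over the list alone; list adjusted p = 0.633); BCL2A1, an anti-apoptotic gene, had a change of 2.09 ± 2.13 (SE, adjusted p = 0.543). It was at least 3.51 without growing replicate 2 and -0.76 without growing replicate 1, passing in opposite directions (adjusted p = 0.0284 and 0.0421) on a senescent SD of 0.004, so neither shows a difference. That list was 0.58 log2 units higher at the median in growing replicate 2 than in growing replicate 1. It passed without growing replicate 2 (adjusted p = 0.0106, 3 higher), while without growing replicate 1, 3 members were higher and 4 lower.

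Collagen and matrix genes were lower in senescent cells. Of 29 tested, 10 fell, 1 rose and 18 did not pass (16 and 1 adjusted over the list alone), with a median change of -0.49 (camera, adjusted p = 7.01e-09, and adjusted p = 0.517 with an estimated correlation). The fibrillar collagen COL5A1 changed by -2.01 ± 0.19 (SE, adjusted p = 0.031), the basement membrane collagens COL4A1 and COL4A2 by -2.01 ± 0.15 and -1.99 ± 0.13 (SE, adjusted p = 0.0242 and 0.0228), and COL12A1, which binds collagen fibrils, by -1.86 ± 0.10 (SE, adjusted p = 0.0173). Decorin (DCN), a proteoglycan that binds collagen and TGF-beta, rose by 0.99 (adjusted p = 0.0405). COL1A1, the main fibrillar collagen of scar, had a change of -0.17 ± 0.08 that did not pass at a level near the top of the scale (log2 14.19 in growing cells, SE, adjusted p = 0.249), and its 4 probe sets ranged from -1.20 to -0.17; as the mean of its probe sets it passed (-0.68, adjusted p = 0.0343). Of 22 genes that process collagen, 5 fell and 0 rose (8 and 2 adjusted over the list alone), with a median of -0.30 (camera, adjusted p = 0.00377, and adjusted p = 0.517 with an estimated correlation). The procollagen protease ADAMTS2 fell by 1.73 and the lysyl oxidase homologue LOXL3 by 1.21 log2 units (adjusted p = 0.028 and 0.0234), as did LOXL2 by 0.96 and the prolyl hydroxylase subunits P4HA3 by 0.67 and P4HA1 by 0.61 (adjusted p = 0.0264, 0.0414 and 0.0414). As means over their probe sets P4HA3 and P4HA1 did not pass (-0.33 and -0.30). ADAMTS2 had 3 probe sets from -1.73 to -0.17 and a mean over all probe sets of -0.93 (adjusted p = 0.0462). The transglutaminase TGM2 (1.5, adjusted p = 0.0751) and the enhancer of procollagen cleavage PCOLCE (-1.38, adjusted p = 0.0749) did not pass. By limma with the block, 0 genes of either list passed, with 20 and 9 at an unadjusted p under 0.05. The falls numbered 4 matrix genes and 1 processing gene without growing replicate 2, where DCN was not called.

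Proteases that break down matrix lay higher. Of 20 tested, 6 rose, 0 fell and 14 did not pass (11 and 2 adjusted over the list alone), with a median of 0.93 (camera, adjusted p = 0.0198, and adjusted p = 0.528 with an estimated correlation). The interstitial collagenase MMP1 rose from log2 8.83 ± 1.40 to 14.35 ± 0.06 (SD, n = 2, limma adjusted p = 0.0414). MMP10, a stromelysin, rose by at least 3.68, and the membrane-bound MMP14 and MMP16 by 0.84 and 1.03 (MMP16 at 0.29 without passing as the mean of its probe sets). PLAT rose by 2.12 and the cathepsin CTSL by 1.32 log2 units. None of MMP10, MMP14, MMP16, PLAT and CTSL was called without growing replicate 2. The stromelysin MMP3 had the largest mean difference of the list, 7.12 ± 1.56, and did not pass (SE, adjusted p = 0.0754): it was at least 8.04 within replicate 1, where the growing array lay below log2 4, and 5.28 within replicate 2. It was 5.05 without growing replicate 1 and at least 8.27 without growing replicate 2 (adjusted p = 0.0354 and 0.0336 on the senescent spread). The lysosomal cathepsin CTSS (4.89 ± 0.97, SE, adjusted p = 0.0655) and PLAU did not pass either; CTSS was 3.61 without growing replicate 1 and at least 5.49 without growing replicate 2, where the growing array left lay below log2 4 (adjusted p = 0.0337 and 0.0284 on the senescent spread). The list call was lost without growing replicate 1 (adjusted p = 0.0814). By limma with the block, 0 members passed and 13 had an unadjusted p under 0.05; the adjusted p of MMP1 was 0.0714. Of 9 protease inhibitors, TIMP1, CSTB and TFPI rose and RECK fell (4 and 1 adjusted over the list alone; list adjusted p = 0.569). TIMP1, an inhibitor of metalloproteinases, rose by 0.68 (adjusted p = 0.0421), CSTB, a cathepsin inhibitor, by 0.68 (adjusted p = 0.0442) and TFPI, an inhibitor of blood clotting, by 1.10 (adjusted p = 0.0447). RECK, a membrane inhibitor of metalloproteinases, changed by -1.24 (adjusted p = 0.0231), with 3 of its 4 probe sets lower and a mean over all probe sets of -0.62 (adjusted p = 0.0448). TFPI2 (0.96, adjusted p = 0.234, and 0.0427 at 1.53 without growing replicate 2) and TIMP3 (-0.74, adjusted p = 0.166, and -1.06 without growing replicate 1) did not pass. None of the 4 limma calls, of TIMP1, CSTB, TFPI and RECK, held with the block (adjusted p = 0.0874, 0.0874, 0.0741 and 0.0624). TIMP1 and CSTB were not called without growing replicate 2 either.

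Genes of stellate cell activation and contractility were lower. Of 24 tested, 8 fell, 1 rose and 15 did not pass (13 and 2 adjusted over the list alone), with a median of -0.43 (camera, adjusted p = 0.000416, and adjusted p = 0.517 with an estimated correlation). ACTA2, the smooth muscle actin that marks activated stellate cells, went from log2 14.74 ± 0.17 to 13.41 ± 0.01 (SD, n = 2, limma adjusted p = 0.029); as the mean of its probe sets the change was -0.55 and did not pass (adjusted p = 0.0508). The contractile regulator CNN1 changed by -1.98 ± 0.13 (SE, adjusted p = 0.0228) and the profibrotic cytokine TGFB2 by -1.71 ± 0.17 (SE, adjusted p = 0.0324), while LRRC17 rose by 0.98 (adjusted p = 0.0274). SYNM, an intermediate filament protein, had a change of -1.85 (adjusted p = 0.0979). Under the block limma called 0 members and 16 had an unadjusted p under 0.05. Without growing replicate 2, 3 fell and 0 rose, against 8 and 2 without growing replicate 1. Of 10 genes of quiescence and retinoid storage, limma called 0 over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 (list adjusted p = 0.569); the retinoic acid receptors RARA (-0.62, adjusted p = 0.07) and RARB (-0.58, adjusted p = 0.337), the TGF-beta pseudoreceptor BAMBI (-0.42, adjusted p = 0.346) and the adiponectin receptor ADIPOR1 (0.42, adjusted p = 0.0724) were its members furthest from 0. With 1 array left out, RARB ran from -1.01 to -0.16 and BAMBI from -0.75 to -0.10. The list holds 21 genes, of which 9 were dim, among them LRAT, PPARG and GFAP, and 2 had no probe set used here. Whether those genes changed could not be tested.

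Ligands and adhesion molecules that natural killer and T cells read were in part higher. Of 14 tested, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.34 (camera, adjusted p = 0.107, and adjusted p = 0.517 with an estimated correlation). MICA, a ligand of the activating receptor NKG2D, rose by 1.07 ± 0.14 log2 units (SE, adjusted p = 0.0405), and ULBP2, another such ligand, had a change of 0.19 (adjusted p = 0.525), which was -0.02 without growing replicate 1. The death receptor TNFRSF10A rose by 1.67 ± 0.08 (SE, adjusted p = 0.0167), the adhesion molecule ICAM3 by 1.38 (adjusted p = 0.0324) and CD58, the ligand of CD2, by 0.57 (adjusted p = 0.0469). ICAM1 (-0.66, adjusted p = 0.222) and the PD-1 ligand gene PDCD1LG2 (-1.27, adjusted p = 0.334) did not pass. Both passed without growing replicate 1 (-1.02 and -2.27, adjusted p = 0.0481 and 0.0326), and PDCD1LG2 was at -0.28 without growing replicate 2. By limma with the block, 0 members passed and 7 had an unadjusted p under 0.05. Leaving out growing replicate 2, the list passed (adjusted p = 0.0217) with 2 members higher, and without growing replicate 1, 5 were higher and 3 lower. Of 17 genes of MHC class I antigen presentation, limma called 0 over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 (list adjusted p = 0.734). The peptide transporter TAP1 (0.87, adjusted p = 0.0622), the proteasome subunit PSMB8 (0.76, adjusted p = 0.0748), the transcription factor NLRC5 (-0.78, adjusted p = 0.342, and from -1.36 to -0.20 with 1 array left out) and the peptidase ERAP1 (-0.61, adjusted p = 0.0571, with its other probe set at 0.15) lay furthest from 0, and PSMB8 and ERAP1 passed without growing replicate 1 (adjusted p = 0.0484 and 0.0483).

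Of 24 interferon-stimulated genes, 22 had a higher mean in senescent cells, with a median of 0.82, IFI27 rose by 1.26 (adjusted p = 0.0491) and the GTPase GBP2 fell by 1.64 log2 units (adjusted p = 0.0227; 0 higher and 1 lower adjusted over the list alone). The list did not pass without the block (camera, adjusted p = 0.195) and passed with it (adjusted p = 0.00113), while the adjusted p with an estimated correlation was 0.687. HERC6 (2.48 ± 1.54, SE, adjusted p = 0.354), MX1 (2.01 ± 1.84, SE, adjusted p = 0.5), IFI44 (1.72 ± 1.33, SE, adjusted p = 0.433) and GBP1 (-1.67 ± 0.29, SE, adjusted p = 0.0556) did not pass. MX1 was at -0.18 without senescent replicate 2, where the senescent array left lay below log2 4. HERC6 was 0.91 without growing replicate 1 and 3.81 without senescent replicate 1, and IFI44 was 0.18 without growing replicate 1 and 3.26 without growing replicate 2. The list was higher in both arrays of replicate 2, by a median of 0.84 in growing and 0.75 log2 units in senescent cells. It passed without growing replicate 2 (adjusted p = 0.0232) and without senescent replicate 1 (adjusted p = 0.00177), which both give replicate 2 more weight on the senescent side, and not without growing replicate 1 (adjusted p = 0.982) or senescent replicate 2 (adjusted p = 0.692). IFI27 was not called with either growing array left out, with array medians subtracted or with no filter. With the block limma called 0 members, with 15 at an unadjusted p under 0.05.

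Lysosomal genes lay higher. Of 26 tested, 5 rose, 1 fell and 20 did not pass (14 and 1 adjusted over the list alone). The list median was 0.49 (camera, adjusted p = 0.00377, and adjusted p = 0.528 with an estimated correlation). GLB1, the galactosidase used to stain senescent cells, is on the list and was not among the genes that passed. The sialidase NEU1 rose by 1.93 (adjusted p = 0.0434), the calcium channel MCOLN1 by 1.85 (adjusted p = 0.0497), the cathepsins CTSL and CTSA by 1.32 and 0.61, and the cholesterol carrier NPC2 by 0.91 log2 units. The glucuronidase GUSB fell by 1.31 log2 units (adjusted p = 0.0324), and CTSK had a change of 1.93 (adjusted p = 0.0574, and 0.0452 and 0.0465 without growing replicate 1 and 2). In cholesterol synthesis, SQLE (0.98, adjusted p = 0.0385) and NSDHL (0.64, adjusted p = 0.0497) rose out of 15 tested (7 adjusted over the list alone), with a median of 0.64 (camera, adjusted p = 0.00449, and adjusted p = 0.517 with an estimated correlation), and IDI1 (1.36, adjusted p = 0.0542), FDPS (1.0, adjusted p = 0.053) and MSMO1 (0.96, adjusted p = 0.0537) did not pass. IDI1 and FDPS passed without growing replicate 1 (adjusted p = 0.0483 and 0.0389). That list call was lost without growing replicate 1 (adjusted p = 0.0814). By limma with the block, 0 members of the lysosome or cholesterol list passed, with 15 and 8 at an unadjusted p under 0.05. The 5 lysosomal rises and that of NSDHL were not called without growing replicate 2. The lysosomal median was 0.449 without growing replicate 2 and 0.571 without growing replicate 1, and the cholesterol median 0.745 and 0.664.

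Of 17 oxidative stress genes, PRDX1, GPX1, MT1X and MT2A rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.59 (camera, adjusted p = 0.000416, and adjusted p = 0.517 with an estimated correlation). The metallothioneins MT1X and MT2A, which bind metals and are near-identical to other family members, rose by 1.06 ± 0.08 and 0.79 ± 0.08 log2 units (SE, adjusted p = 0.0257 and 0.0324). HMOX1, the heme oxygenase, had a change of 2.54 ± 0.43 that did not pass (SE, adjusted p = 0.0537), and SRXN1 one of 0.84 (adjusted p = 0.239, from 0.37 to 1.32 with 1 array left out). Under the block limma called 0 members, with 12 at an unadjusted p under 0.05, and 0 passed without growing replicate 2. Among 20 apoptosis regulators, limma called 0 over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 (list adjusted p = 0.405), with BCL2A1 (2.09), PMAIP1 (0.96), BID (0.80) and BCL2L1 (0.51) furthest from 0; PMAIP1 turned to -0.29 and BCL2A1 to -0.76 without growing replicate 1, and the list passed without growing replicate 2 (adjusted p = 0.0325). The 24 ribosomal protein genes tested had a median of 0.05 and limma called 0 over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.909); RPS15 (0.16), RPL30 (0.16), RPL19 (0.15) and RPL32 (0.10) were furthest from 0.

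**Figure D3:**
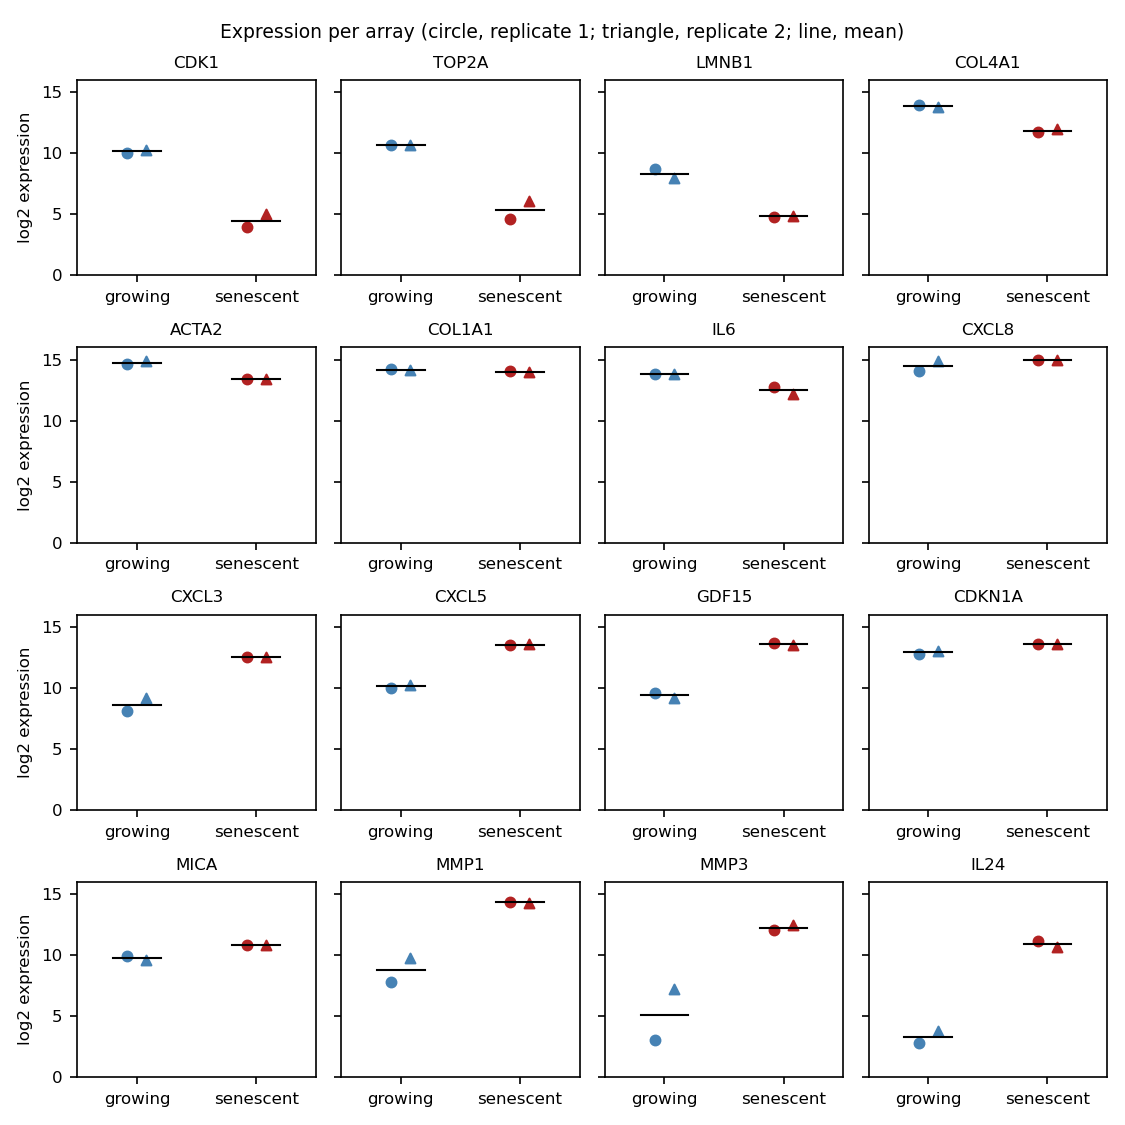
Log2 expression (y axis) of 16 named genes on each of the 4 arrays, growing in blue and senescent in red, with circles for replicate 1, triangles for replicate 2 and a line at the group mean. CDK1 and TOP2A are lower on both senescent arrays, and MMP3 differs between the 2 growing arrays, with a mean of 5.15 ± 2.92 there and 12.27 ± 0.32 in senescent cells (SD, n = 2).

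Markers of hepatocytes, leukocytes, macrophages and endothelium were mostly dim. Of 20 hepatocyte markers 17 were dim and 1 was tested (list adjusted p = 0.693), of 17 leukocyte markers 16 were dim and 0 were tested, and of 15 markers of macrophages 13 were dim, with LYZ tested at a change of at least 1.73 (adjusted p = 0.0631). Of 15 endothelial markers 13 were dim, and TEK fell by 0.92 log2 units (adjusted p = 0.0381; list adjusted p = 0.27). Of 12 cholangiocyte and epithelial markers 6 were dim, and of the 4 tested SPP1 rose and KRT7 fell by 3.03 log2 units (adjusted p = 0.0362; list adjusted p = 0.463). Of 12 portal fibroblast and mesothelial markers 8 were dim, and of the 4 tested CALB2 rose by 2.92 (adjusted p = 0.0359; list adjusted p = 0.405). Of 10 smooth muscle and pericyte markers 2 were dim, and of the 8 tested LMOD1 fell by 3.41 and MCAM by 1.03 log2 units (adjusted p = 0.0235 and 0.0302; list adjusted p = 0.115). The macrophage list holds 1 tested gene, LYZ, so its list test is that of LYZ. The smooth muscle list passed with the stricter filter (camera, adjusted p = 0.0311), with the mean of probe sets (camera, adjusted p = 0.0406) and with fry (adjusted p = 0.044). SPP1, TEK, CALB2, LMOD1 and MCAM were not called without growing replicate 2. None of these calls held with the replicate block, where the adjusted p was 0.0692 for TEK, 0.0689 for SPP1, 0.0621 for KRT7, CALB2 and LMOD1, and 0.0665 for MCAM. Adjusted over the list alone, 1 rose and 2 fell among epithelial, 0 and 1 among endothelial and 1 and 0 among macrophage markers. The macrophage marker is LYZ, the only one tested, so its p was left unadjusted. Among portal fibroblast markers 1 rose and 1 fell, and among smooth muscle markers 0 rose and 3 fell.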

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

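The alternatives below were chosen before the data were examined. The count of 950 genes was 1132 with the stricter filter, 963 with low values raised, 1099 after quantile normalization, 1072 after subtracting array medians, 819 with the mean of probe sets, 1031 with trend and robust, and 1327 of 18416 over all probe sets, where 856 differed at least 2-fold (369 higher, 487 lower). With no filter it was 383 (211 higher, 172 lower), with 180 at least 2-fold (82 higher, 98 lower), over 19740 genes tested. Leaving out each array in turn gave 0 to 1524 genes, 0 to 892 higher and 0 to 632 lower, and 0 to 866 at least 2-fold, 0 to 447 higher and 0 to 419 lower; the 0 came without either senescent array, where the growing pair alone gives the spread and the lone array is assumed to vary like it, and the highest without growing replicate 1. Without growing replicate 2, 395 genes passed. The 11 lists that passed (6 higher, 5 lower) became 9 to 16, 4 to 11 higher and 5 to 7 lower, with an array left out, 13 with no filter, 13 with the mean of probe sets, and 12 with the stricter filter. Fry, which asks another question, whether a list's genes move one way against no change, passed 14. With an estimated correlation 0 passed, 0 higher and 0 lower. The cause was not tested beyond these.

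With the replicate number as a block, the pairing of preparations left 40 genes (22 higher, 18 lower), all at least 2-fold (40; 22 higher, 18 lower), and 2963 at an unadjusted p under 0.05. The block takes 1 of the 2 residual degrees of freedom. It passed 12 lists, adding the interferon-stimulated genes (adjusted p = 0.00113), and changed no other list call. Of 113 named genes, 57 passed, and 43 of these did not pass with the block. In the alternatives 0 of the 57 turned direction. The block, the left-out arrays and the raised low values could not have turned a gene that had passed. Both filter settings and trend and robust leave the change itself as it is. At most quantile normalization, subtraction of medians and the mean of probe sets could alter a direction. With no filter, 33 of the 57 did not pass. Named genes that had not passed did so in 19 cases without growing replicate 1, 11 without growing replicate 2, 10 with the stricter filter, 7 after quantile normalization, 4 with the mean of probe sets, 3 after subtracting medians, 3 with trend and robust and 2 with low values raised. The mean of probe sets, dim ones included, moved some that had not passed by over 1.5 times: RFC3 to -0.69, FUCA1 to 1.15, SPATA18 to 0.68, GAS1 to -0.29, TIMP3 to -0.49, RARA to -0.25, ERAP1 to -0.10, IFI44 to 0.88, IDI1 to 0.70, CDKN2B to -0.13, CXCL8 to 1.003, ULBP2 to 0.45 and RPS15 to 0.09. With 1 array left out, RPL30 ran from 0.10 to 0.21, RPL32 from 0.06 to 0.14, ICAM1 from -1.02 to -0.30 and TFPI2 from 0.39 to 1.53. Of the genes named after their values were seen, 53 passed. The call was lost for 47 with the block, 30 with no filter, 7 with the mean of probe sets, 10 without growing replicate 1, 32 without growing replicate 2 and 53 without either senescent array. None turned direction. The mean of probe sets moved DCN to 0.58, LRRC17 to 0.50, GUSB to -0.67, TEK to -0.52, MCAM to -0.51, LYZ to 1.04, AKR1C1 to 1.03, PDK4 to 1.64, ENPP2 to 1.46, CXCR4 to 2.19, CEMIP to -1.36, PTN to -2.34, PDLIM3 to -1.04 and MYH10 to -3.47.

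The results that turned direction were 7 named genes and several lists that had not passed. Over the fits with an array left out, log2 changes ran from -1.37 to 0.03 for GAS1, -0.76 to 4.94 for BCL2A1, -0.29 to 2.22 for PMAIP1, -0.66 to 0.14 for CDKN2B, -0.017 to 0.4 for ULBP2, -0.43 to 1.996 for CDKN1B and -0.18 to 4.20 for MX1. The turn came without growing replicate 1 for GAS1, BCL2A1 (adjusted p = 0.0421), PMAIP1, CDKN2B and ULBP2, without growing replicate 2 for CDKN1B and without senescent replicate 2 for MX1. The extremes of BCL2A1 (4.94) and MX1 (-0.18) rest on a lone array below log2 4. List adjusted p-values after the turn were 0.97 for quiescence and 0.943 for endothelial cells with no filter, 0.971 for ribosomal proteins after subtracting medians and 0.847 with the mean of probe sets, 0.533 for cholangiocytes with the mean of probe sets, and 0.295 for cell cycle inhibitors with fry. With an array left out, the adjusted p ran from 0.0719 to 0.968 for growth factors, 0.568 to 0.968 for MHC class I (0.901 without senescent replicate 2), 0.0106 to 0.739 for NF-kappaB targets (0.475 where it turned), 0.0325 to 0.77 for apoptosis regulators, 0.288 to 0.97 for hepatocytes and 0.568 to 0.968 for ribosomal proteins. The cause was not tested. The signal over background limits what dim genes can show: 92 called genes lay below log2 4 on both arrays of a group (57 in growing, 35 in senescent cells).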

Other observations

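Genes outside the lists, chosen after their values were seen, also differed between the groups. The aldo-keto reductases AKR1B10 (5.13 log2 units, adjusted p = 0.0201), AKR1C1 (2.53, adjusted p = 0.0295) and AKR1C2 (2.62, adjusted p = 0.031), which reduce aldehydes and steroids, rose in senescent cells; the probe sets of the near-identical AKR1C1 and AKR1C2 cannot be assumed to separate them. PDK4, which restrains pyruvate oxidation, rose by 4.88 (adjusted p = 0.0244), clusterin (CLU) by 3.51 (adjusted p = 0.0264) and the phospholipase PLA2G4A by 2.85 (adjusted p = 0.0194). ENPP2, which makes lysophosphatidic acid, rose by 2.88 (adjusted p = 0.0086), the chemokine receptor CXCR4 by at least 3.15 (adjusted p = 0.011), and SERPIND1 and AADAC, both best known from hepatocytes, by at least 3.88 and 4.26. ENPP2, CXCR4, SERPIND1 and AADAC passed with the replicate block as well (adjusted p = 0.0406 each), and AKR1B10 (0.0621), AKR1C1 and AKR1C2 (0.0678), PDK4 (0.0624), CLU (0.0624) and PLA2G4A (0.0621) did not.

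Among genes that were bright in growing cells, the oxytocin receptor OXTR went from log2 12.90 to 9.32 (adjusted p = 0.0149), the hyaluronan-degrading factor CEMIP from 13.70 to 10.98 (adjusted p = 0.011) and the adhesion protein TENM2 from 12.52 to 9.29 (adjusted p = 0.00774). The growth factor PTN changed by -3.66 (adjusted p = 0.028), the transcriptional regulator ID4 by -3.54 (adjusted p = 0.0395) and PTGIS, which makes prostacyclin, by -2.48 log2 units (adjusted p = 0.0434). As the mean of its probe sets ID4 was -2.39 and PTGIS -1.61, and neither passed. LMCD1 (-3.16, adjusted p = 0.0191), PDLIM3 (-2.81, adjusted p = 0.0205) and MYH10, a nonmuscle myosin (-2.12, adjusted p = 0.0204), fell too. With the replicate block TENM2 (adjusted p = 0.0406) and CEMIP (adjusted p = 0.0428) passed and the others did not, at 0.0553 for OXTR, 0.0624 for PTN, 0.0687 for ID4, 0.0537 for PTGIS, 0.0585 for LMCD1 and MYH10 and 0.0621 for PDLIM3.

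All tests in the rest of this part were chosen after the results were seen. A set of 80 genes was at least 2 log2 units higher in growing replicate 2 than in growing replicate 1, with 32 lower. In the senescent pair 18 were that far apart. Of the 80, 0 passed between the groups, but so wide a gap in the growing pair makes a call very unlikely. That 0 cannot show whether the state of growing replicate 2 reached the calls. RNA of senescent cells mixed into growing replicate 2 would put it between the others, yet 73.8% of the 80 genes (59) were above both senescent arrays. Degraded RNA would widen the gap between the 3′ and 5′ actin controls, which was 0.73 log2 units there and 0.87, 0.83 and 0.94 on the other arrays, at levels near the top of the scale. Of 28 tested immediate-early genes, written down without those that had first drawn attention, 25 were higher in growing replicate 2, with a median of 1.07 at percentile 100 of 10000 random lists of like level, and -0.01 at percentile 22.31 in the senescent pair. An acute response to serum or handling, with EGR1 at 2.14 and DUSP1 at 1.65, may therefore be part of growing replicate 2. Which event set it off was not tested. EGR1, and ZFP36 at 2.12, are themselves among the 80 genes, so the list is not fully separate from them.

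Interferon-stimulated genes were higher in both arrays of replicate 2, 19 of 24 in both groups, by medians of 0.84 in growing and 0.75 log2 units in senescent cells. Noise of dim probe sets would give random lists matched on level the same medians, but the lower of the 2 percentiles among 10000 such lists was 100. For the 12 members at log2 8 or more, the growing and senescent differences were averaged per gene, and the median of these averages was 0.27. That is another measure than the separate medians above. Of the 12, 7 were higher in both. What both arrays of a number share, in the cells, the culture or the day of hybridisation, stays open, and no biological explanation was tested.

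Of the listed histone genes normally expressed in S phase, 7 were tested and all had higher mean signals in senescent cells. Of these, 3 passed singly and 1 with the block. The list had a camera adjusted p = 0.528 with an estimated correlation, and 7 more members were dim. Which forms of the transcripts the probe sets read was not tested, so the total amount of histone transcript is not known from them. The low level in growing replicate 2 alone would leave replicate 1 flat, but the 7 list members had a median change of 3.15 within replicate 1 and all 7 were higher within both. Cross-hybridisation among like histone genes was not tested and stays open, since most dim members were flat. The probe sets used for H2AC6, H2BC5 and H2BC21 carry a name suffix for sequence shared between genes (_s or _x). Those for H1-2, H2BC4, H2BC12 and H4C8 carry no such suffix, at changes of 4.77, at least 3.2, 2.83 and 4.83. The suffix alone does not settle what a probe set reads. No biological explanation was tested.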
